A study of Homo sapiens with 6 samples.

How the data were processed

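RNA sequencing measured gene expression in 6 libraries of KYSE30 cells, 3 of control cells and 3 of cells overexpressing HOXC9. Libraries were assigned to groups by their sample labels. The deposited table lists 63241 genes by Ensembl identifier, of which 42640 have a symbol. In 33018 genes no library had a count.

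Per the labels' protocols, total RNA was extracted with TRIzol and its quality was measured before library construction. The submitters' processing notes name fastp 0.23.4, HISAT2 2.2.1, StringTie 2.2.1, RSEM 1.3.3, DESeq2 1.42.0 and the GRCh38 build, without a role or an order. The annotation release and the strandedness of the counting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The authors deposited an estimated count per gene and library, which is not scaled between libraries. Between 29.5% and 30.5% of the non-zero values in a library are not whole, as estimates that divide reads between genes can be. The authors also deposited TPM values (transcript abundance scaled to a fixed total) per library, which each sum to about 1000000, and their mean TPM per group. The authors' fold change is a ratio of control over HOXC9, and the deposited log2 value is the log2 of that ratio. The deposited p-value and adjusted p-value of each gene come from the authors' own test, and 47434 adjusted p-values in the authors' deposited table are exactly 1. The authors list 1 length in bases per gene.

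The depth was 18970057, 19258384 and 20061666 estimated counts in the control libraries and 19201887, 19829100 and 20222726 in the HOXC9 libraries. At this depth a count of 0 allows up to 3 counts, and between 15145 and 15402 genes had at least 10 counts in a library.

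Estimated counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15, which left 15342 genes. Libraries were scaled by TMM. The groups were compared by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. The threshold on the adjusted p was 0.05. Fold changes are HOXC9 over control, and levels are CPM, read counts divided by the TMM-scaled library size, as mean ± SD of 3 libraries.

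The level of HOXC9 was also compared by an exact two-sided permutation test. The 35 gene lists held 1034 distinct genes. They were tested by camera (limma 3.58.1) on log-CPM with a prior count of 2, with a preset correlation between genes of 0.01 and with one estimated from the data, and adjusted over the 35 lists. The rotation test fry was run beside it. Of the 35 lists, 18 were called by camera with the preset correlation, 17 higher and 1 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.198. By fry 12 were called in 1 direction and 26 in either direction. Of the 12, 9 were among camera's 18 calls. The others were the basal squamous keratinocyte and NOTCH pathway lists, lower, and the apoptosis regulators, higher.

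Some members had a newer symbol in the table than in common use, and list members were matched through the synonyms of a RefSeq gene table. Positions were taken by gene identifier from GENCODE release 29 (GRCh38), which matched 58228 identifiers. Genes that share a symbol with another entry, 2106 in all, were kept as separate entries.

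The groups, the tests, the lists and the rule for named genes were fixed before the data were examined. The rule named HOXC9, the 12 other protein-coding genes with the largest rise and the 12 with the largest fall, and the 5 with the smallest p in each direction. Of the genes ranked by size, each passed the threshold, had a mean of at least 5 CPM in the higher group and did not overlap between the groups. It also named up to 4 members of each list with the smallest adjusted p, whether or not they passed, and further genes fixed in advance, among them HOXC6, HOXC8, HOXC10 and MEIS1. Genes named outside the rule are the further changed members of a list, the entries that share a symbol and the genes in the closing section, and they were chosen after their values were seen.

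The test was tested on simulated data, drawn from the means and library sizes of these libraries with 200 genes changed by known folds. For HOXC9 against control, with 15332 genes tested, it recovered 69.4% of 49 genes changed 1.5-fold, 81.3% of 48 changed 2-fold, 95.9% of 49 changed 3-fold and 100% of 48 changed 4-fold. Of its 183 calls 8.20% were not changed genes, and with no gene changed it called 6 of 15341. Without a filter on low counts 17.9% of 207 calls among 28376 genes were not changed genes. With 1 list raised 1.5-fold, camera called that list and 1 other, 2 in all. The simulated genes were drawn independently of each other, so this does not test the preset correlation.

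The alternatives were DESeq2 1.42.0 and limma-voom, other scalings (median of ratios, upper quartile, total counts), no filter, a CPM of at least 1 in 3 libraries, the replicate number as a block, and each library left out in turn. A test against a 1.5-fold change, HOXC9 left out of the table, and limma-trend on log2(TPM + 1) and log2(TPM + 0.1) were also run. The constant added to TPM shrinks the log2 fold changes of genes with a low TPM, so those values are not plain TPM ratios. After the data had been seen, a correction for GC content per library (a loess fit with a span of 0.5), the sum of entries that share a symbol, and a fit without mitochondrially encoded genes were added. GC content was known for 95.8% of the genes tested.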

Results

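Gene expression was measured by RNA sequencing in KYSE30, an established human cell line of esophageal squamous cell carcinoma, a cancer of the squamous epithelium that lines the esophagus. The libraries fell into 2 groups: 3 control libraries and 3 libraries of cells that overexpressed HOXC9, a homeobox transcription factor of the HOXC cluster. The labels give the control genotype as WT, and the authors' column names call the groups Lv_NC and Lv_OE. If only the overexpressing cells carry a vector, its effects cannot be told apart from those of HOXC9. The labels do not say that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The libraries held between 18970057 and 20222726 estimated read counts, and between 22843 and 23408 genes had a value above 0 in each. The series has 1 comparison, which asks how the expression of other genes changes when HOXC9 is raised in these cells.

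HOXC9 itself was higher in all 3 overexpressing libraries than in any control. Its level rose from 1.28 ± 0.551 to 7.18 ± 1.71 CPM (normalised read counts, mean ± SD, n = 3 in each group), a 5.62-fold difference (log2 fold change 2.49, SE 0.27). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 0.000298, and the exact two-sided permutation test of the level gave p = 0.10, the smallest that 3 libraries against 3 allow. Estimated counts of the gene were 36, 18 and 19.9 in the controls and 111, 132 and 184 with overexpression, so the control level rests on few reads. The fold change depends on the unit: in TPM the values were 2.46, 1.25 and 2.05 against 5.06, 5.94 and 7.97. By limma-trend the log2 fold change was 1.33 on log2(TPM + 1) and 1.69 on log2(TPM + 0.1) (adjusted p = 0.0301 and 0.0358). The added constant itself lowers the log2 fold change at such levels, more so with 1 than with 0.1. The gene (ENSG00000180806) lies on the plus strand of chromosome 12 at 53994895 to 54003337 (GRCh38, GENCODE release 29).

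**Figure D1:**
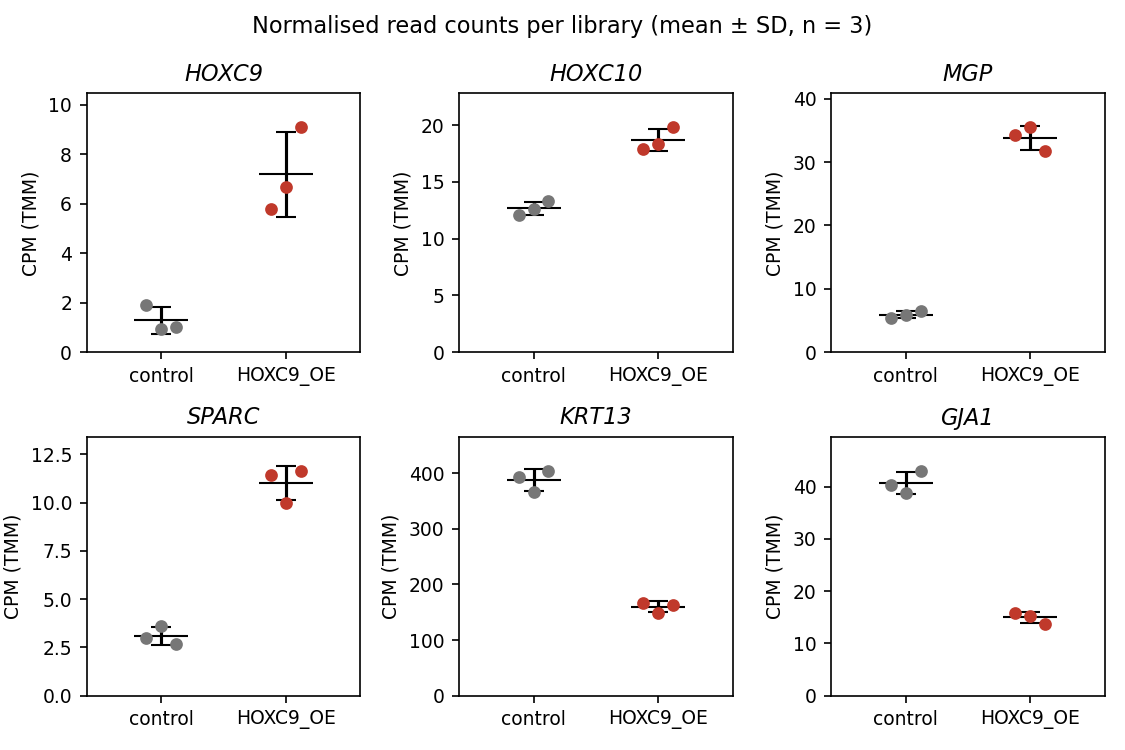
Normalised read counts (CPM after TMM scaling) of HOXC9, HOXC10, MGP, SPARC, KRT13 and GJA1 in each library, with points for libraries and bars for the mean ± SD of n = 3 per group. HOXC9, HOXC10, MGP and SPARC were higher in all 3 HOXC9_OE libraries than in any control, and KRT13 and GJA1 were lower.

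Of the other measured genes of the HOXC cluster, HOXC10 and HOXC13 rose with HOXC9. HOXC10 (chromosome 12, 53985065 to 53990279) rose from 12.7 ± 0.599 to 18.7 ± 1.00 CPM (log2 fold change 0.56, SE 0.09, n = 3 in each group). HOXC13 (53938765 to 53946544) rose from 15.1 ± 1.43 to 20.9 ± 1.89 CPM (log2 fold change 0.47, SE 0.10). Of the 23 measured HOX genes other than HOXC9, these 2 rose, none fell and 21 did not pass. With p adjusted over the list alone, 3 were higher and 1 lower. HOXC8 and HOXC6, which neighbour or overlap HOXC9, did not pass: HOXC8 had a log2 fold change of 0.56 (SE 0.33, below 1 CPM in both groups) and HOXC6 one of 0.83 (SE 0.29). HOXC6 shares 73 exonic bases with HOXC9, so its reads are uncertain. HOXA3 (-0.47, SE 0.12) and HOXA13 (0.44, SE 0.12) did not pass either. The list was called higher by camera (adjusted p = 0.00295) and lost the call at adjusted p = 0.376 with an estimated correlation. It was not called by fry (adjusted p = 0.165). None of the 14 measured HOX cofactors and posterior HOX regulators passed edgeR's test (0 by DESeq2 and limma-voom as well, and 0 at an unadjusted p under 0.05). The DNA-binding partner MEIS1 had a log2 fold change of -0.15 (SE 0.13), MEIS2 one of -0.19 (SE 0.09) and SUZ12 one of -0.16 (SE 0.08), and camera gave an adjusted p of 0.352. The call of HOXC13 was lost without control library 1, control library 3 or HOXC9_OE library 1 (adjusted p between 0.0837 and 0.146). The calls of HOXC10 and HOXC13 were both lost by limma-trend on log2(TPM + 1) and on log2(TPM + 0.1) (adjusted p at most 0.1996 for HOXC10 and 0.138 for HOXC13).

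**Figure D2:**
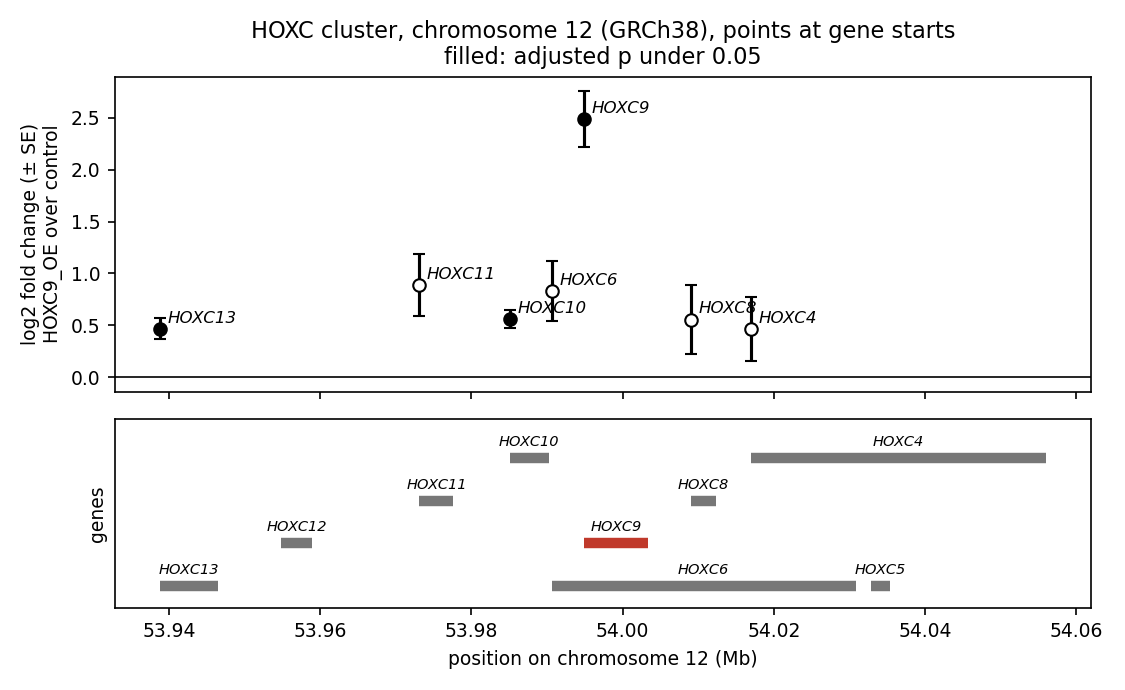
Log2 fold change of the measured HOXC genes, HOXC9_OE over control (points with SE, placed at the gene start), above a map of the cluster on chromosome 12 (GRCh38, position in Mb). HOXC9 had a log2 fold change of 2.49, and the other measured HOXC genes lay between 0.47 and 0.89, of which HOXC10 and HOXC13 passed an adjusted p of 0.05.

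Among protein-coding genes that passed with a mean of at least 5 CPM in the higher group, MGP had the largest rise with HOXC9. MGP, which encodes the calcification inhibitor matrix Gla protein, rose 5.74-fold from 5.88 ± 0.558 to 33.8 ± 1.92 CPM (log2 fold change 2.52, SE 0.10). SPARC, a collagen-binding matrix glycoprotein, rose 3.56-fold to 11.03 ± 0.901 CPM, and SPP1, which encodes the secreted phosphoprotein osteopontin, rose 2.81-fold from 32.3 ± 2.43 to 90.6 ± 6.49 CPM. The connexin genes GJB6 and GJB2 rose 3.51-fold and 2.41-fold, whereas a further connexin gene, GJA1, fell from 40.7 ± 2.17 to 14.97 ± 1.10 CPM (log2 fold change -1.44, SE 0.08). OLFM4 (3.42-fold), the matrix protease gene ADAMTS15 (2.94-fold), the heme oxygenase gene HMOX1 (2.83-fold), the adhesion gene L1CAM (2.63-fold) and SFMBT2 (2.42-fold) also rose. The placental alkaline phosphatase genes ALPP (2.72-fold) and ALPG (2.74-fold) are near-identical neighbours on chromosome 2 that can share reads, so the value of each is uncertain. EMP1, a membrane protein gene of squamous epithelium, was among the genes with the smallest p and rose 1.68-fold to 952 ± 18.0 CPM. The call of ADAMTS15 was lost by limma-trend on log2(TPM + 1), where its log2 fold change was 0.61 (adjusted p = 0.0515), and on log2(TPM + 0.1) (0.0675). GJB6 and ALPG lost theirs on log2(TPM + 0.1) alone (0.0706 and 0.0597).

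At the same minimum level, PTPRZ1 had the largest fall, a log2 fold change of -1.79 (SE 0.26), at 1.90 ± 0.807 CPM with HOXC9. KRT13, a keratin of differentiated esophageal and oral epithelium, fell from 388 ± 19.4 to 159 ± 9.92 CPM (log2 fold change -1.28, SE 0.06, n = 3 in each group; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 9.44e-07). The transcription factor gene SOX21 had a log2 fold change of -1.71 (SE 0.12) and went from 20.3 ± 0.699 to 6.17 ± 0.908 CPM. The adhesion genes CTNND2 (log2 fold change -1.60, SE 0.13) and PCDH19 (-1.49, SE 0.11), the keratin gene KRT23 (-1.45, SE 0.14) and CLCA2 (-1.31, SE 0.17) fell as well. NPR3, a natriuretic peptide receptor gene, fell by 1.12 on the log2 scale, the neurotrophin receptor gene NGFR fell by 1.10, IGFBP2 fell by 1.07 and the protease inhibitor gene SPINK5 fell by 1.01. The call of SPINK5 was lost without control library 1 (adjusted p = 0.0511). On both TPM scales the calls of PTPRZ1, PCDH19, CLCA2, NPR3 and SPINK5 were lost (adjusted p between 0.0513 and 0.154), and the log2 fold change of PTPRZ1 was -0.81 on log2(TPM + 1). Falls of comparable size below 5 CPM in both groups, those of TNFRSF19 and MMP10, are given with their lists.

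**Figure D3:**
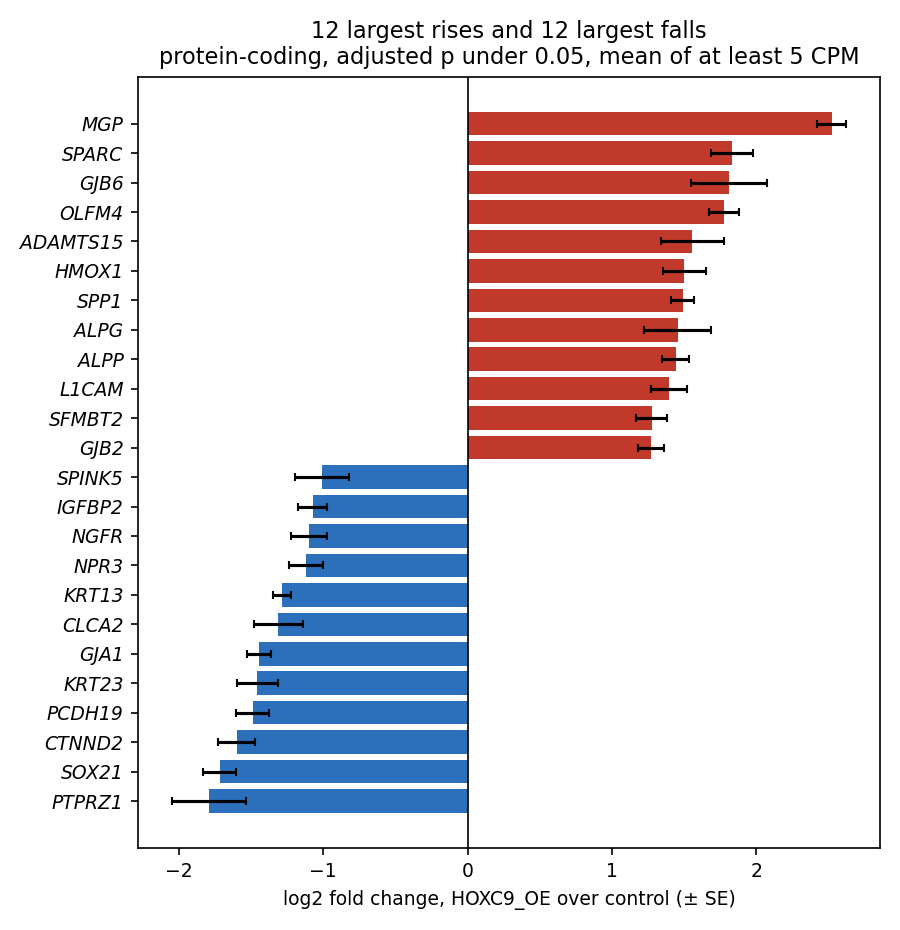
Log2 fold change (HOXC9_OE over control, bars with SE, n = 3 per group) of the 12 protein-coding genes with the largest rise and the 12 with the largest fall, among genes other than HOXC9 at an adjusted p under 0.05, with a mean of at least 5 CPM in the higher group and no overlap between the groups. Values run from -1.79 for PTPRZ1 to 2.52 for MGP.

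Across all 15342 genes tested by edgeR's quasi-likelihood test, 479 changed at an adjusted p under 0.05, 279 higher and 200 lower with HOXC9. The share that was higher was 58.2%. Changes were mostly modest: the median absolute log2 fold change of the changed genes was 0.50, and 81 of them, 40 higher and 41 lower, changed at least 2-fold. All 479 had values that did not overlap between the groups, as did 20.7% of all genes tested, against the 10% that chance gives for 3 against 3. The count fell to 293, 275 or 231 without control library 1, 2 or 3 and to 267 without HOXC9_OE library 1, and with no filter on low counts it was 1012, of which 45.3% were higher. It was 129 or 125 by limma-trend on log2(TPM + 1) or log2(TPM + 0.1), of which 70.5% or 69.6% were higher, and 42 or 45 of the 86 named calls other than HOXC9 were lost there. Among genes named by the rule, calls lost on both scales and given below were those of FN1, FSTL1, CDKN2B, PTGS2, FST, FGFR3, AREG, EREG, DLC1, FAS, CYP1A1 and PECAM1, and those of GRHL1, TJP3, OAS1, DTX3L, TAPBP, BMP7, ID2, HES2, NOTCH1, TGFB2 and LHFPL6. The others were SLC2A3, MT-CO3, MT-ND6, FADS1, BTG2, PMAIP1, CYP26B1, ABCC3, ABCG2, CSF1R and KRT18, and MMP10 lost its call on log2(TPM + 0.1) alone. Genes named outside the rule were not followed singly on these scales, which lost 354 and 358 of the 479 calls. Most of them were not followed with each library left out either, and 256 calls were lost without control library 3. In 5 of the 6 changed table entries that share a gene symbol with another entry (both entries of WASH6P, and ZNF271P, PLCXD1 and PLEKHA8P1), the call was lost when the entries of a symbol were summed, so these are uncertain.

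Some keratinocyte genes rose, others fell, and most did not pass. Among 24 measured basal squamous keratinocyte genes, 3 rose, 6 fell and 15 did not pass. In the test adjusted over the list alone, 5 were higher and 9 lower. The basal keratin gene KRT15 fell from 144 ± 8.20 to 74.1 ± 5.20 CPM (log2 fold change -0.96, SE 0.07), and KRT6A (-0.76, SE 0.07; close copies KRT6B and KRT6C can share its reads), the squamous lineage factor gene SOX2 (-0.61, SE 0.06) and COL17A1, a hemidesmosome collagen gene (-0.46, SE 0.05), fell too. NGFR and the integrin gene ITGA6 were the other 2 that fell, and S100A2 and the laminin gene LAMA3 were among the 3 that rose. Camera did not call this list (adjusted p = 0.210), whose median log2 fold change was 0.00 and whose mean was -0.11. The rotation test fry called it lower (adjusted p = 0.0230). Among 19 measured squamous differentiation and cornified envelope genes, 5 rose, 2 fell and 12 did not pass. When adjusted over the list alone, 7 were higher and 2 lower. EMP1, the envelope precursor SPRR1A (6.83 ± 0.511 to 14.9 ± 0.190 CPM), the kallikrein protease genes KLK6 and KLK5 and the envelope gene IVL rose. In contrast, KRT13 and KRT4, keratins of the layers above the basal one, fell. Camera called this list higher (adjusted p = 0.0330), but not with an estimated correlation (0.263) or without HOXC9_OE library 3 (0.0555). Nor did it after a correction for GC content (0.0907) or with the replicate number as a block (0.0793). The rotation test fry called the squamous differentiation list higher (adjusted p = 0.00658). Of 29 measured epithelial junction genes, GRHL1 (log2 fold change 0.43, SE 0.09) and TJP3 (0.34, SE 0.08) rose, none fell and 27 did not pass; TJP1 (0.22, SE 0.06) and OVOL2 (0.61, SE 0.18) were among those. If adjusted over the list alone, 4 were higher. Camera called the junction list higher (adjusted p = 0.0191, or 0.371 with an estimated correlation, 0.143 without HOXC9_OE library 3 and 0.101 after the GC correction). By fry the junction list had an adjusted p of 0.0914. The call of GRHL1 was lost without control library 2 or 3 or HOXC9_OE library 1 or 2 (adjusted p between 0.0563 and 0.0967), and that of TJP3 without control library 1, 2 or 3 or HOXC9_OE library 1 (0.107 to 0.180) and after the GC correction (0.0503).

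Some mesenchymal and matrix genes rose, and most members of these lists did not pass. Among 23 measured mesenchymal and epithelial-mesenchymal transition (EMT) genes, 10 rose, none fell and 13 did not pass. Adjusted over the list alone, 13 were higher and 1 lower. The log2 fold change was positive in 16 of the 23 and ran from -0.70 to 1.83, that of SPARC. AXL, a receptor tyrosine kinase gene, rose from 51.1 ± 2.55 to 96.3 ± 6.82 CPM (log2 fold change 0.91, SE 0.07, n = 3 in each group; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.72e-05). SPARC, the fibronectin gene FN1 (166 ± 11.3 to 226 ± 6.92 CPM), FSTL1 (log2 fold change 0.44, SE 0.07), LOXL2, ITGA5, COL5A1 and TGFBI rose too. The intermediate filament gene VIM rose from a low level, 5.34 ± 0.319 to 8.38 ± 0.827 CPM. Camera called the list higher (adjusted p = 1.31e-06; adjusted p = 0.198 with an estimated correlation), and 11 members were higher without HOXC9_OE library 3. Of 30 measured matrix protease, integrin and invasion genes, 4 rose, 2 fell and 24 did not pass, with 7 higher and 2 lower adjusted over the list alone. The urokinase gene PLAU (84.2 ± 5.29 to 133 ± 2.28 CPM), the protease inhibitor genes TIMP2 (log2 fold change 0.55, SE 0.06) and SERPINE2 (0.62, SE 0.08) and the integrin gene ITGB6 rose. The stromelysin gene MMP10 (-1.71, SE 0.27, below 4 CPM) and the collagen receptor gene ITGA2 fell. Camera called this list higher (adjusted p = 0.00434, or 0.198 with an estimated correlation). Fry called the mesenchymal and the protease lists higher too (adjusted p = 0.00658 and 0.0282). Of 26 measured targets of YAP and TEAD, the transcriptional effectors of the Hippo pathway, 5 rose, none fell and 21 did not pass, and 11 were higher adjusted over the list alone. AXL, DLC1 (0.60, SE 0.10), TGFB2 (0.77, SE 0.16), LHFPL6 (0.36, SE 0.08) and RBMS3 were the 5. CCN1, CCN2, ANKRD1, AMOTL2, AJUBA and LATS2 were among the 21 that did not pass. Camera called the list higher (adjusted p = 1.10e-05, or 0.240 with an estimated correlation), and so did fry (adjusted p = 0.0313). The calls of TGFB2 and LHFPL6 were lost without control library 2, control library 3 or HOXC9_OE library 2, and that of LHFPL6 also without control library 1 or HOXC9_OE library 1 (adjusted p between 0.0576 and 0.0979 for TGFB2 and between 0.0534 and 0.145 for LHFPL6).

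**Figure D4:**
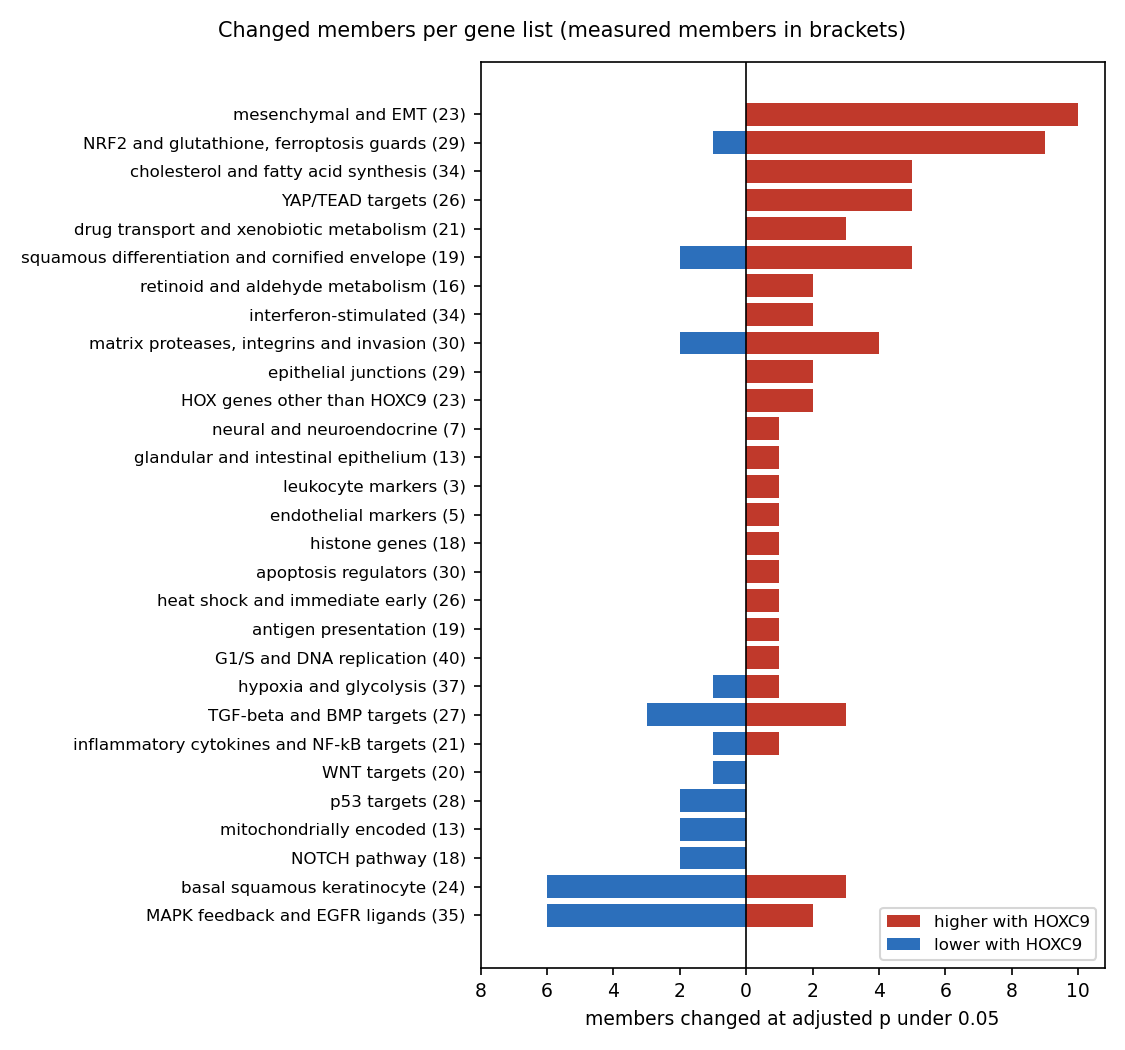
Number of members of each gene list that changed at an adjusted p under 0.05, higher with HOXC9 to the right and lower to the left, with measured members in brackets. Lists with no changed member are not drawn, and the mesenchymal and EMT list had the most changed in 1 direction, 10 of 23 higher and 0 lower.

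Some growth factor and signalling genes changed, in both directions. Among 35 measured MAPK feedback genes and EGFR ligands, 2 rose, 6 fell and 27 did not pass. With p adjusted over the list alone, 6 were higher and 11 lower. The EGFR ligand genes AREG (396 ± 64.2 to 241 ± 38.0 CPM; log2 fold change -0.72, SE 0.12) and EREG (-0.80, SE 0.15), the feedback inhibitor genes SPRY1 (-0.67, SE 0.09) and DUSP6, and the receptor genes FGFR3 (-0.54, SE 0.08) and FGFR2 fell. The receptor genes EGFR (2936 ± 87.9 to 3421 ± 103 CPM) and ERBB3 rose. Camera did not call the list (adjusted p = 0.110), but called it lower without control library 2 (0.0103). In the 18 measured NOTCH pathway genes, NOTCH1 (-0.60, SE 0.12) and HES2 (-0.59, SE 0.11) fell, none rose and 16 did not pass, among them DTX4 (0.51, SE 0.12) and JAG1 (-0.28, SE 0.08). In the test adjusted over the list alone, 1 was higher and 3 lower (camera, adjusted p = 0.0732, 0.0306 without control library 1 and 0.0280 after the GC correction). The NOTCH list was called lower by fry (adjusted p = 0.0313). The TGF-beta and BMP list and the WNT list hold ligands and receptors of each pathway as well as targets. Of 27 measured genes of the TGF-beta and BMP list, PMEPA1 (0.72, SE 0.07), TGFB2 and TGFB1 rose. FST (-0.60, SE 0.11), BMP7 (-0.43, SE 0.08) and ID2 (-0.42, SE 0.08) fell, and 21 did not pass. Adjusted over that list alone, 4 were higher and 5 lower, and camera gave an adjusted p of 0.840 in the lower direction. The median and mean log2 fold change were 0.00 and 0.01. Of 20 measured genes of the WNT list, TNFRSF19 fell (-1.96, SE 0.28, from 3.37 ± 0.807 to 0.858 ± 0.241 CPM) and none rose. The other 19 did not pass, among them FZD7 (0.23, SE 0.09), WNT7B (0.25, SE 0.09) and FZD8 (0.78, SE 0.34). When adjusted over the list alone, 1 was lower (camera, adjusted p = 0.236). TNFRSF19 passed in every alternative, with log2 fold changes between -2.22 and -0.67. Calls were lost without control library 2, control library 3 or HOXC9_OE library 1 for NOTCH1 and HES2, and without control library 3 or HOXC9_OE library 1 for BMP7 and ID2; HOXC9_OE library 2 also decided NOTCH1 and ID2, and control library 1 ID2. The adjusted p without those libraries lay between 0.0531 and 0.0903 for NOTCH1, 0.0558 and 0.0780 for HES2, 0.0639 and 0.0810 for BMP7, 0.0521 and 0.0821 for ID2 and 0.0576 and 0.0979 for TGFB2, whose call was lost without control library 2 or 3 or HOXC9_OE library 2.

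Some genes of iron, redox and lipid metabolism rose, and most did not pass. Among 29 measured NRF2 and glutathione genes and ferroptosis guards, 9 rose, 1 fell and 19 did not pass. If adjusted over the list alone, 11 were higher and 1 lower. HMOX1 rose from 2.78 ± 0.339 to 7.88 ± 0.620 CPM, the ferritin subunit genes FTL (log2 fold change 0.47, SE 0.06) and FTH1 (2173 ± 103 to 2804 ± 168 CPM) rose. So did the thioredoxin reductase gene TXNRD1 (0.34, SE 0.05), NQO1, ABCC3 and ME1. TRIM16L, which rose too (0.58, SE 0.05), is a close copy of TRIM16, and the ferritin genes have many processed pseudogenes, so their reads can be shared. The 1 that fell, ACSL4, loads membranes with polyunsaturated fatty acids and is not itself a ferroptosis guard. It fell from 98.6 ± 1.24 to 67.7 ± 11.01 CPM. Camera called the list higher (adjusted p = 0.000133, or 0.198 with an estimated correlation), and so did fry (adjusted p = 0.00695). Of 34 measured cholesterol and fatty acid synthesis genes, 5 rose, none fell and 29 did not pass, with 15 higher and 1 lower adjusted over the list alone. The squalene synthase gene FDFT1 (167 ± 4.64 to 214 ± 7.60 CPM, log2 fold change 0.36, SE 0.05) was among those that rose. So were the desaturase genes SCD (0.31, SE 0.05) and FADS1 (0.29, SE 0.05) and MSMO1 (0.37, SE 0.06). Camera called the synthesis list higher (adjusted p = 4.45e-07, or 0.263 with an estimated correlation), and so did fry (adjusted p = 0.0230). In 16 measured retinoid and aldehyde metabolism genes, ALDH1A3 (741 ± 10.03 to 1033 ± 30.2 CPM) and CYP26B1 (0.64, SE 0.15) rose, none fell and 14 did not pass, among them ALDH3B1 (0.39, SE 0.11) and RDH10 (0.21, SE 0.07). Adjusted over the list alone 5 were higher (camera, adjusted p = 0.00920, or 0.371 with an estimated correlation and 0.0638 after the GC correction, and fry, adjusted p = 0.0642). In 21 measured drug transport and xenobiotic genes, CYP1A1 (0.76, SE 0.11), ABCC3 (0.40, SE 0.08) and ABCG2 (0.30, SE 0.07) rose, none fell and 18 did not pass, ABCC5 (-0.28, SE 0.08) among them. Adjusted over the list alone, 3 were higher and 2 lower (camera, adjusted p = 0.0760, and 0.0372 without control library 1). Without control library 2 the calls of SCD, FADS1, MSMO1, ABCC3, ABCG2 and CYP26B1 were lost. Without control library 3 those of SCD, FADS1, ABCC3, ABCG2 and CYP26B1 were lost, and without HOXC9_OE library 1 those of FADS1, ABCC3, ABCG2 and CYP26B1, and without control library 1 those of ABCC3, ABCG2 and CYP26B1. CYP26B1 was also lost without HOXC9_OE library 2 or 3, and ABCG2 without library 2. The adjusted p there was 0.0558 for MSMO1 and lay between 0.0511 and 0.0560 for SCD, 0.0592 and 0.107 for FADS1, 0.0584 and 0.120 for ABCC3, 0.0686 and 0.261 for ABCG2 and 0.0646 and 0.164 for CYP26B1. The call of CYP26B1 was also lost by DESeq2 and limma-voom (adjusted p = 0.0753 and 0.0550), and that of ABCG2 by median-of-ratios scaling (0.0509).

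Few mitochondrially encoded transcripts passed, and none rose. Of the 13 genes, MT-CO3 (11074 ± 533 to 9604 ± 464 CPM; log2 fold change -0.21, SE 0.05) and MT-ND6 (-0.28, SE 0.07) fell, none rose and 11 did not pass, MT-CO1 (-0.25, SE 0.06) and MT-ATP6 (-0.23, SE 0.06) among them. With p adjusted over the list alone, 11 were lower. Adjusted over all genes, 7 were lower without HOXC9_OE library 3 and 5 after the GC correction. The list's median log2 fold change was -0.21 (camera, adjusted p = 4.59e-05, or 0.371 with an estimated correlation, and fry, adjusted p = 0.0923). Mitochondrially encoded genes took 10.8%, 10.1% and 10.4% of the counts of the control libraries against 9.85%, 9.24% and 8.54% of those with HOXC9. The calls of MT-CO3 and MT-ND6 were each lost without any 1 of the control libraries or without HOXC9_OE library 2, and that of MT-ND6 also without library 1 (adjusted p between 0.0584 and 0.197 for MT-CO3 and between 0.0502 and 0.176 for MT-ND6). MT-CO3 also lost its call with upper quartile scaling (adjusted p = 0.0522). Nuclear-encoded genes of oxidative phosphorylation had 0 of 40 past the threshold by edgeR, DESeq2 or limma-voom and 0 at an unadjusted p under 0.05. COX7C (0.14, SE 0.07), NDUFA1 (0.17, SE 0.09), COX6A1 (0.11, SE 0.06) and CYCS (-0.10, SE 0.06) had the smallest p. The median was 0.05 (camera, adjusted p = 0.0376, or 0.600 with an estimated correlation, 0.0887, 0.109 and 0.762 without control library 1, control library 2 or HOXC9_OE library 3, 0.0834 after the GC correction and 0.0646 with no filter). Fry gave an adjusted p of 0.376. For 47 cytosolic ribosomal protein genes, which have many pseudogene copies, 0 passed by edgeR, DESeq2 or limma-voom, 0 had an unadjusted p under 0.05 and the median was 0.07 (camera, adjusted p = 0.00212; adjusted p = 0.594 with an estimated correlation, and 0.256 without HOXC9_OE library 3). By fry the adjusted p of the ribosomal protein list was 0.303. RPL19, RPL24, RPL11 and RPS15 had log2 fold changes of 0.10 (SE 0.05), 0.13 (SE 0.06), 0.08 (SE 0.04) and 0.10 (SE 0.06). Among 37 hypoxia and glycolysis genes, the peptide hormone gene ADM rose (0.40, SE 0.07), the glucose transporter gene SLC2A3 fell (-0.61, SE 0.12) and 35 did not pass, HK1 (-0.20, SE 0.06) and ANGPTL4 (1.11, SE 0.35) among them. The counts adjusted over the list alone were the same, 1 higher and 1 lower (camera, adjusted p = 0.197, and 0.0496 without control library 1). The call of ADM was lost without control library 2 or 3 (adjusted p between 0.0539 and 0.0855), and that of SLC2A3 without HOXC9_OE library 1 (0.0847).

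Few interferon and antigen presentation genes passed. Of 34 measured interferon-stimulated genes, OAS1 (31.3 ± 1.25 to 39.9 ± 2.68 CPM; log2 fold change 0.35, SE 0.08) and DTX3L (0.33, SE 0.07) rose, none fell and 32 did not pass, IFIT1 (0.30, SE 0.08) among them. Adjusted over all genes, 5 were higher without HOXC9_OE library 3 and 6 after the GC correction. Adjusted over the list alone 6 were higher, and the median was 0.19 (camera, adjusted p = 4.59e-05, or 0.368 with an estimated correlation, and fry, adjusted p = 0.110). Of 19 measured antigen presentation genes, TAPBP rose (0.31, SE 0.07), none fell and 18 did not pass, B2M (0.19, SE 0.05), CALR (0.19, SE 0.05) and PSMB8 (1.08, SE 0.39, below 1 CPM) among them. In the test adjusted over the list alone, 3 were higher (camera, adjusted p = 0.00295; adjusted p = 0.296 with an estimated correlation). Of 21 measured inflammatory cytokine genes and NF-kB targets, TNFAIP2 rose (0.52, SE 0.06), the prostaglandin synthase gene PTGS2 fell (-0.99, SE 0.18; 78.5 ± 22.7 to 39.6 ± 7.30 CPM) and 19 did not pass, LCN2 (1.28, SE 0.32) and NFKBIA (0.23, SE 0.07) among them. Adjusted over that list alone 4 were higher and 1 lower (camera, adjusted p = 0.00212 in the higher direction, or 0.198 with an estimated correlation). Fry called the antigen presentation and the cytokine lists higher (adjusted p = 0.0313 and 0.0338). The calls of OAS1, DTX3L and TAPBP were each lost without any 1 of the control libraries or without HOXC9_OE library 1, and that of DTX3L also without library 2 (adjusted p between 0.0541 and 0.139 for OAS1, 0.0577 and 0.148 for DTX3L and 0.0973 and 0.141 for TAPBP).

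Cell cycle lists held almost no changed gene. Of 40 measured G1/S and DNA replication genes, the CDK inhibitor gene CDKN2B rose (23.2 ± 1.75 to 33.7 ± 2.33 CPM; log2 fold change 0.54, SE 0.09), none fell and 39 did not pass, CDK6 (-0.28, SE 0.10), GINS2 (-0.16, SE 0.07) and MCM7 (-0.11, SE 0.05) among them. The count adjusted over the list alone was also 1 (camera, adjusted p = 0.352; 0.0372 and 0.0229, lower, without control library 1 or HOXC9_OE library 3). None of 40 G2/M and mitosis genes passed edgeR's test over all genes or adjusted over the list alone, and DESeq2 and limma-voom called 0. CDK1 (-0.23, SE 0.07) and KIF20A (0.14, SE 0.06) were the 2 with an unadjusted p under 0.05, and FOXM1 (0.12, SE 0.06) and CDC20 (0.11, SE 0.05) came next (camera, adjusted p = 0.845). Among 28 p53 targets, the death receptor gene FAS (22.1 ± 2.08 to 13.95 ± 1.16 CPM; -0.66, SE 0.10) and BTG2 (-0.42, SE 0.09) fell, none rose and 26 did not pass, FBXW7 (-0.28, SE 0.08) and PERP (-0.18, SE 0.05) among them. When adjusted over the list alone, 1 was higher and 6 lower (camera, adjusted p = 0.0867, and 0.0160 without control library 1). Of 30 measured apoptosis regulators, PMAIP1 rose (0.44, SE 0.10), none fell and 29 did not pass, TNFRSF1A (0.23, SE 0.06), BMF (0.40, SE 0.12) and BAX (0.21, SE 0.07) among them. If adjusted over the list alone, 1 was higher (camera, adjusted p = 0.132, and fry, adjusted p = 0.0452 in the higher direction). In 26 heat shock and immediate early genes, HSPB1 rose (0.45, SE 0.07), none fell and 25 did not pass, EGR1 (-0.53, SE 0.13), EGR3 (-1.35, SE 0.37) and FOSB (-0.75, SE 0.26) among them. Adjusted over the list alone, 1 was higher and 2 lower (camera, adjusted p = 0.0911; 0.0103 and 0.0361, lower, without control library 2 or HOXC9_OE library 3, and 0.0465 after the GC correction). None of 27 unfolded protein and integrated stress response genes passed edgeR's test, over all genes or adjusted over the list alone, and DESeq2 and limma-voom called 0. ATF4 (0.16, SE 0.05), PSAT1 (-0.18, SE 0.06), EDEM1 (0.16, SE 0.06) and CEBPB (0.38, SE 0.16) were the 4 with an unadjusted p under 0.05 (camera, adjusted p = 0.132, and 0.0300 without HOXC9_OE library 1). Of 18 measured histone genes, H2AC6 rose (0.40, SE 0.07), none fell and 17 did not pass, H2BC8 (1.05, SE 0.34) and H4C14 (0.69, SE 0.31) among them. With p adjusted over the list alone, 1 was higher (camera, adjusted p = 0.00269, or 0.368 with an estimated correlation, and fry, adjusted p = 0.0798). The call of BTG2 was lost without any 1 of the control libraries or without HOXC9_OE library 1 or 2 (adjusted p between 0.0572 and 0.180), and that of PMAIP1 without control library 1 or 2 or HOXC9_OE library 1 or 2 (0.0867 to 0.142).

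Each list of markers of other cell types held at most 1 changed gene. Of 15 fibroblast and stromal markers 5 could be tested and 0 passed by edgeR, DESeq2 or limma-voom, with 3 at an unadjusted p under 0.05. COL3A1 had 0.465 ± 0.193 CPM in control and 1.12 ± 0.234 with HOXC9. MMP2, COL1A1 and C1R had log2 fold changes of 0.28 (SE 0.10), 0.37 (SE 0.13) and -0.07 (SE 0.40). Adjusted over the list alone 3 were higher (camera, adjusted p = 0.0374; adjusted p = 0.368 with an estimated correlation). The call was lost without control library 2 or 3 (0.0674 and 0.231), without HOXC9_OE library 1, 2 or 3 (0.491, 0.172 and 0.159), after the GC correction (0.0834) and with no filter (0.119). The stromal list was not called by fry either (adjusted p = 0.171). Of 5 measured endothelial markers, PECAM1 rose (2.44 ± 0.163 to 4.80 ± 0.516 CPM), none fell and 4 did not pass, among them CDH5 (0.46, SE 0.17), ENG (0.59, SE 0.38) and ERG (-0.55, SE 0.39). In the test adjusted over the list alone, 1 was higher (camera, adjusted p = 0.0870, and 0.0161 without HOXC9_OE library 2). Of 18 leukocyte markers only 3 could be tested: CSF1R rose (3.98 ± 0.482 to 6.31 ± 0.465 CPM), CD68 (0.41, SE 0.16) and CORO1A (0.34, SE 0.31) did not pass. When adjusted over the list alone, 2 were higher (camera, adjusted p = 0.00888, or 0.240 with an estimated correlation, and fry, adjusted p = 0.0270, higher). Of 13 measured glandular and intestinal markers, KRT18 rose (log2 fold change 0.23, SE 0.05), none fell and 12 did not pass, VIL1 (-1.19, SE 0.35), KRT8 (0.17, SE 0.05) and CEACAM6 (0.36, SE 0.15) among them. Adjusted over that list alone 2 were higher and 1 lower, and its mean of -0.02 lay opposite to its median of 0.00 and to camera's direction, higher (adjusted p = 0.201). Of 7 measured neural and neuroendocrine markers, L1CAM rose (8.85 ± 1.52 to 23.2 ± 2.07 CPM), none fell and 6 did not pass, MAP2 (-0.29, SE 0.09), SYT1 (-0.45, SE 0.15) and ENO2 (-0.26, SE 0.19) among them. If adjusted over the list alone, 1 was higher and 2 lower. Its median of -0.12 and its mean of 0.03 differed in sign (camera, adjusted p = 0.4996 in the lower direction). The call of CSF1R was lost without control library 2 or 3 or HOXC9_OE library 1 or 2 (adjusted p between 0.0506 and 0.132), and that of KRT18 without any 1 of the control libraries or without HOXC9_OE library 1 (0.0506 to 0.172).

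The libraries separated by group on the first principal component of log2 CPM, which held 33.9% of the variance. Control libraries lay between -19.4 and -15.6 on it, and those with HOXC9 at 10.6, 9.57 and 31.5. HOXC9_OE library 3 stood apart from the other 2 of its group on the second component (19.7% of the variance), at 20.3 against -16.0 and -20.8. This depends on the genes used: over the 500 most variable genes HOXC9_OE library 3 was at 10.8, near control library 1 at 8.99, and HOXC9_OE library 2 lay farthest out, at -13.5. Pearson correlations between libraries lay between 0.990 and 0.991 within the controls, 0.988 and 0.991 within the HOXC9 group, and 0.984 and 0.989 between the groups. No pair agreed within sampling noise: the chi-square per degree of freedom of a pair was at least 2.95.

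**Figure D5:**
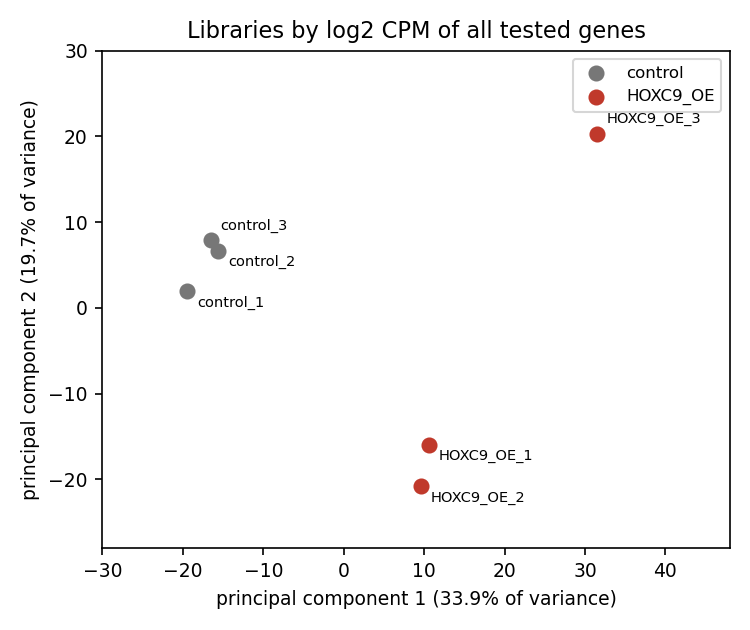
Scores of the 6 libraries on the first and second principal components of log2 CPM over all tested genes, with the percent of variance on each axis and points coloured by group. The 3 control libraries lie at or below -15.6 on the first component, the 3 HOXC9_OE libraries at or above 9.57, and HOXC9_OE library 3 lies apart at 31.5 and 20.3.

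The authors' deposited table gives its fold change as control over HOXC9, so genes it marks as up were higher in control. The authors' deposited table marks 447 genes as significant, 240 higher in control and 207 higher with HOXC9. The marked genes are those that have an unadjusted p under 0.05 and at least a 1.5-fold difference in the authors' deposited table. Of them 184 have an adjusted p under 0.05 in the authors' deposited table, and 74 have one of exactly 1. Counted by adjusted p under 0.05, the authors' deposited table holds 495 genes, 284 higher with HOXC9. All 479 genes called here have the same direction in the authors' deposited table, and 432 of them have an adjusted p under 0.05 there.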

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

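The value below was computed only after the data had been seen. The ratio of the deposited count to the deposited TPM of a gene follows the length that the authors' estimate used for it. Relative to the median gene of each library, this ratio for HOXC9 was 0.359, 0.352 and 0.2298 in the controls and 0.541, 0.541 and 0.543 in the libraries with HOXC9. The log2 difference between the groups was 0.82, and 0.319% of the 14103 genes with at least 10 counts in each library differed by as much. The size of the HOXC9 fold change therefore depends on whether counts or TPM are compared.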

How the results depend on the processing

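The GC correction, the summed entries and the fit without mitochondrially encoded genes were chosen only after the results were seen. HOXC9 passed the threshold in all 19 alternatives that tested it, with log2 fold changes of 1.33 to 2.89, and of 2.28 to 2.89 when 1 library was left out. Against 479 changed genes, 1012 were called with no filter, which kept all 479 and added 46 outside the genes tested before. limma-trend called 129 on log2(TPM + 1) and 125 on log2(TPM + 0.1), and leaving out 1 library gave 231 (without control library 3) to 626 (without HOXC9_OE library 3). Against 81 genes changed at least 2-fold, no filter gave 181 and a test against a 1.5-fold change 41. On the TPM scales 22 and 32 genes passed with a log2 difference of at least 1. The constant added there shrinks the differences of low genes, so this is a stricter limit than 2-fold. The share of changed genes that were higher, 58.2%, was 45.3% with no filter, 70.5% and 69.6% on the TPM scales, and 51.3% to 62.1% with 1 library left out. The added genes are a small part of the rise with no filter, and the causes of these differences were not tested. Camera called 0 lists with an estimated correlation and 15 to 22 with 1 library left out, against 18. Fry called 12 lists, 9 of them among the 18. DESeq2 called 532 genes, limma-voom 467, the other scalings 464 to 486 and the GC-corrected fit 646. Of 86 changed genes named by rule other than HOXC9, 59 passed with every library left out in turn and 38 in every alternative run, and none reversed. The TPM scales lost 42 and 45 of the 86 calls. Libraries with equal numbers deviated together weakly (correlations 0.0852, 0.0610 and 0.0237, against -0.0865 to 0.0196 for the other pairs), and the numbers were not taken as pairs. With the replicate block 554 genes were called, 53.1% of them higher, and 17 lists. The squamous differentiation list (adjusted p = 0.0793 by camera) and ABCG2 (adjusted p = 0.0567 by edgeR) lost their calls there. Depth limits low genes: HOXC9 had 18 to 36 counts in the controls.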

Other observations

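The term enrichment, the counts of stromal transcripts, the comparison across HOX clusters and the splits for the number of changed genes were tests chosen only after the results were seen. Matrix and adhesion terms passed among genes higher with HOXC9, and some of them among lower genes too. The hypergeometric test used for terms takes genes as independent, and terms were not tested in any alternative. Camera with an estimated correlation between genes called 0 of the 35 lists. Of 143 tested genes of the collagen-containing extracellular matrix, 22 rose, 7.86 times the number expected (hypergeometric test, Benjamini-Hochberg adjusted p = 1.50e-10). Among them were the basement membrane collagen genes COL4A1 and COL4A2, COL12A1, and the galectin genes LGALS1 and LGALS3. Of 129 focal adhesion genes in the KEGG set, 17 rose (4.70 times the number expected, adjusted p = 2.47e-05), among them the actin genes ACTB and ACTG1, which have many pseudogene copies, and the actin crosslinkers FLNA and ACTN1. In total 9 KEGG terms and 51 gene ontology terms passed among the higher genes.

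Among genes lower with HOXC9, 0 KEGG terms and 9 gene ontology terms passed an adjusted p of 0.05. Of 318 cell surface genes 19 fell (4.34 times the number expected, adjusted p = 0.000222), among them the receptor genes FZD1, NOTCH1, FGFR2 and FGFR3. The same term passed among the higher genes, where 20 rose (3.21 times the number expected, adjusted p = 0.000916). Of 50 cornification genes 6 fell, the keratin genes KRT4, KRT6A, KRT13, KRT15 and KRT23 and the inhibitor gene SPINK5 (adjusted p = 0.0481). In the squamous differentiation and cornified envelope list, by contrast, 5 genes rose, SPRR1A and IVL among them, and 2 fell. The collagen-containing matrix term also passed among the lower genes: 9 of its 143 genes fell, among them COL17A1, COL4A5 and COL4A6 (adjusted p = 0.0481). So did extracellular matrix organization, of whose 112 genes 16 rose and 8 fell (adjusted p = 6.96e-07 and 0.0481), and cell adhesion, of whose 238 genes 16 rose and 12 fell (adjusted p = 0.00257 and 0.0481).

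The mesenchymal and EMT genes that rose could have come from admixed stromal cells, from a GC content trend or from HOXC9_OE library 3 alone. Counts of the abundant fibroblast transcripts COL1A2, DCN and LUM summed to 4 over the HOXC9 libraries, which argues against admixed stromal cells as the whole source. Among members that did not pass, the fibroblast markers COL3A1 (2.39-fold) and COL1A1 (1.29-fold) leaned higher, and camera called the stromal list higher (adjusted p = 0.0374). That call was lost by camera with an estimated correlation (adjusted p = 0.368) and without any 1 of 5 libraries (0.0674 to 0.491). It was also lost after the GC correction and with no filter. Of the 10 called members, 10 stayed higher after the GC correction and 10 without HOXC9_OE library 3. Of all 479 calls, 467 and 455 were kept there, so keeping the call is not particular to these members. A response to HOXC9 remains open as a hypothesis, and differences between the cultures unrelated to HOXC9 were not tested.

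HOXC10 and HOXC13 rose beside HOXC9 on chromosome 12. Reads of the HOXC9 transcript are an unlikely source, since the longest stretch of identical bases shared with a HOXC10 or HOXC13 transcript was 17, and at least 92.3% of the log2 fold change was kept after the GC correction. The 4 other measured HOXC genes had a median log2 fold change of 0.69 against 0.12 for 17 HOXA and HOXB genes (exact two-sided permutation p = 0.00434), and genes of a cluster are not independent. Without HOXC6, which shares exonic bases with HOXC9, the median was 0.56 and the exact permutation p was 0.0596. A rise across the HOXC cluster may therefore be followed up as a hypothesis, and it rests in part on HOXC6.

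Fold changes rose with GC content across genes (Spearman's rho 0.234, genes not being independent). Without HOXC9_OE library 3 rho was 0.0231, and it lay between 0.184 and 0.338 without any other library. A pair of libraries within the HOXC9 group had an absolute rho of 0.501. The trend is consistent with a GC bias that varies between libraries, mainly in HOXC9_OE library 3.

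The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. Every other split also mixes control and HOXC9_OE libraries, so a group difference would widen its within-group spread and lower its calls. The real split gave 479 changed genes against at most 1 in any other, 81 changed at least 2-fold against at most 1, and 18 lists against at most 12; in each case 1 split, the real one, gave a result as large.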
